A study of Homo sapiens with 9 samples.

How the data were processed

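Total RNA was measured in 9 libraries of the oral squamous cell carcinoma line UPCI-SCC-040, 3 without TGF-β1, 3 after 48 h and 3 after 72 h at 5 ng/ml. Per the labels' protocols, RNA was extracted on silica columns and libraries were made with a NEBNext Ultra RNA kit. Per the labels, the deposited values are a count of reads per gene and library on genome build hg38, not normalized. The submitters' processing notes list bcl2fastq 2.17.1.14, FastQC 0.11.5, STAR 2.5.2a and featureCounts 1.5.0-p1. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Overlapping and antisense genes, and near-identical copies such as AKR1C1 and AKR1C2, LGALS7 and LGALS7B, the histone genes and the protocadherins, may therefore share or lose reads.

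The files held 58233 Ensembl gene identifiers. Symbols, gene types and coordinates came from GENCODE release 29 (GRCh38), in which 57895 identifiers were found and 338 were not. The unmatched identifiers held 0.0145% to 0.0202% of counts per library and were kept by identifier. Library totals ran from 12544690 to 20438727 counts. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom of 8.99 to 159 over genes with at least 20 counts, so no library was a copy of another.

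Groups, replicate numbers and passages came from the sample labels. Gene tests used edgeR 4.0.16 under R 4.3.3, with TMM scaling, the filterByExpr filter, all 9 libraries in 1 model of group with 6 residual degrees of freedom, robust quasi-likelihood F tests and Benjamini-Hochberg adjustment within each comparison at 0.05. CPM values use TMM-scaled library sizes and are given as mean ± SD of 3 libraries. Standard errors of log2 fold changes are approximate, computed as the absolute log2 fold change over the square root of F. Levels of genes tied to the sex of the donor are not reported. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 36 lists, with an estimated correlation and with fry beside it. fry asks whether a list's genes move on balance in 1 direction, without comparing them with other genes. The lists overlap, so a gene can count in several of them and calls of lists are not separate results.

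The tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the 8 highest and 8 lowest log2 fold changes at each time against control among genes with a symbol, an adjusted p under 0.05, at least 10 CPM on average in the higher group and no overlap between the groups' libraries. For 72 h against 48 h it took 5 of each, and none qualified. It added, for each list, the 3 members with the largest mean change among those past the threshold at both times with at least 1 CPM. The rule gave free places to members past the threshold at 1 of the times by size of change, then to others by the smallest p at 72 h. It also added TGFB1, TGFBR1, TGFBR2, VIM, CDH1, CDH2, FN1, SNAI1, SNAI2 and ZEB1. Members of lists that were not called are partly left out, as the rule allowed, and some genes that the rule took are not reported here. Genes and families outside the rule are named as such.

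Same-numbered samples share a passage per the labels, so the replicate number was used as a pairing in an alternative fit with 4 residual degrees of freedom. As a check, deviations from the group means correlated between same-numbered libraries at 0.11, 0.08 and 0.12 (control and 48 h, replicates 1, 2 and 3), 0.04, 0.11 and 0.10 (control and 72 h) and -0.03, 0.49 and 0.49 (48 h and 72 h), and 7 of 9 libraries correlated best with their own number. These values alone would not establish the pairing, which rests on the labels.

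The gene test was tested on simulated data drawn from the real means, library sizes and dispersions, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. At 48 h against control it recovered 4.48%, 29.9% and 78.8% of these with 3 false calls among 15117 genes, at 72 h against control 1.49%, 34.3% and 80.3% with 5 among 15121, and at 72 h against 48 h 1.49%, 38.8% and 78.8% with 6 among 15121. Changes of 2-fold or less were thus often missed in these simulations, where few genes changed. They gave each gene the same dispersion in all groups. In the data the median SD of a gene (log2) was 0.150 in controls, 0.239 at 48 h and 0.300 at 72 h. Recovery at 72 h against 48 h may therefore be overstated.

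Alternatives were DESeq2 1.42.0, its size factors or upper-quartile factors within edgeR, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate block, a fit of only the 2 groups compared, a 2-fold threshold, and omission of each library or replicate number in turn. Corrections for GC content and exon length, list counts without each library, and families of genes defined by symbol were chosen after seeing the data. GC values were at hand for 15399 of the 15440 tested genes. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.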

Results

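RNA-seq gene counts were analysed for UPCI-SCC-040, a cell line established from a squamous cell carcinoma of the tongue, with and without transforming growth factor beta 1 (TGF-β1), a cytokine that signals through SMAD proteins. The 9 libraries of total RNA formed 3 groups of 3, namely untreated controls, cells given 5 ng/ml TGF-β1 for 48 h and cells given that dose for 72 h. Each group held 1 library from each of passages 12, 13 and 8, which are replicates 1, 2 and 3. Library totals ran from 12544690 to 20438727 counts, and 15440 genes had enough counts to be tested. The series concerns prognostic factors in the progression of oral squamous cell carcinoma, and the comparisons ask which genes differ in expression after treatment at each time and between the times. TGF-β1 was given in medium without serum, whereas the growth medium held serum. The titles of the controls carry a time of 0 h, and the labels do not state that controls were kept without serum, so TGF-β1, serum withdrawal and time in culture change together in each comparison with control. Nothing beyond the passage marks the replicates as separate cultures, so p-values measure only the spread between these samples.

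Controls and treated libraries lay apart on the first principal component of log2 CPM (counts scaled to library size), which held 59.6% of the variance. Controls lay between -75.2 and -63.7, and the 6 treated libraries between 9.13 and 84.4. Pearson correlations between libraries of a group, across genes, were 0.989 to 0.990 in controls, 0.970 to 0.982 at 48 h and 0.951 to 0.984 at 72 h. The 72 h library of replicate 3 stood apart from the other treated libraries, at 84.4 on the first component and -42.7 on the second, where 48 h replicate 3, of the same passage, was at -24.4 and the other 4 treated libraries at 6.60 to 41.0. In that library the nuclear long noncoding RNA MALAT1 took 1.54% of counts, against 0.437% and 0.409% in the other 72 h libraries, and transcripts of ribosomal protein genes took 1.02%, against 1.57% and 1.81%. In controls, ribosomal protein transcripts took 2.45% to 2.86% of counts.

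**Figure D1:**
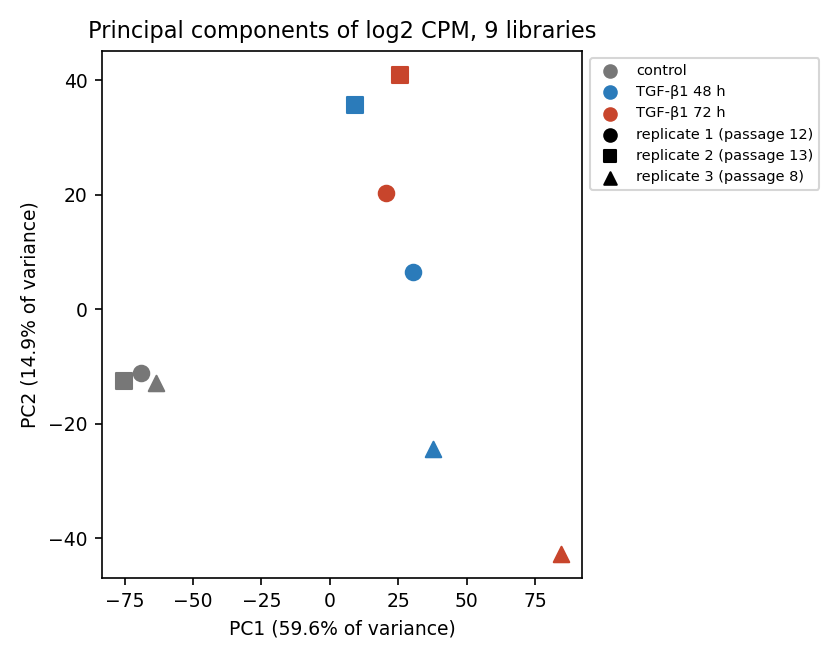
First and second principal components of log2 CPM (axes in component units, with the percent of variance) for the 9 libraries; colour marks the group and marker shape the replicate. Controls sit between -75.2 and -63.7 on the first component and the treated libraries between 9.13 and 84.4.

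After 48 h of TGF-β1, genes of cholesterol and fatty acid synthesis, many interferon-stimulated genes and part of the genes of the matrix and its integrin receptors were higher than in controls. Genes of DNA replication, mitosis and histones were lower, as were the cytokine genes IL6 and IL1B and the genes of the ID transcriptional regulators. Of 15440 genes, 4779 (31.0%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2301 higher and 2478 lower, and 2158 of the 4779 changed at least 2-fold. Which direction held more calls depended on the scaling, with 2575 higher and 2205 lower under upper-quartile factors. At an unadjusted p under 0.05 there were 6690 genes, against 772 by chance. In 8286 genes (53.7%) the 3 treated libraries did not overlap the 3 controls, against 10% by chance. The count fell to 2860, 2631 and 2991 without control 1, 2 and 3, and to 2837 without 48 h replicate 1.

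Lipid synthesis genes rose nearly throughout. SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834, plus strand, GRCh38), the desaturase that makes monounsaturated fatty acids, went from 162 ± 16.5 CPM in controls to 3584 ± 850 at 48 h (SD, n = 3 each), a log2 fold change of 4.47 ± 0.25 (approximate SE; adjusted p = 4.19e-05). INSIG1, which retains SREBP in the endoplasmic reticulum, rose by 3.39 ± 0.42 (adjusted p = 0.00119). Of 31 cholesterol and fatty acid synthesis genes, 28 rose and 1 fell, and the counts were the same adjusted over the list alone. The list median was 1.83, with a camera adjusted p of 1.21e-20, and the call was lost with an estimated correlation between genes (adjusted p = 0.135).

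Interferon-stimulated genes were prominent among the largest rises. IFI44L went from 3.02 ± 1.65 to 281 ± 263 CPM (log2 fold change 6.54 ± 1.51, adjusted p = 0.0138, n = 3), and MX1, an antiviral GTPase, from 28.1 ± 13.1 to 672 ± 538 CPM (4.58 ± 1.09, adjusted p = 0.0155). MX2 rose by 5.27 ± 1.22, XAF1 by 4.96 ± 1.34, TRIM22 by 4.78 ± 1.29 and OAS1, a sensor of double-stranded RNA, by 4.55 ± 1.00 on the log2 scale (adjusted p = 0.014, 0.0248, 0.0243 and 0.0116). Of 37 tested interferon-stimulated genes 17 rose and 0 fell, and 19 rose adjusted over the list alone. Their median was 2.29 (camera adjusted p = 2.48e-08; adjusted p = 0.534 with an estimated correlation, and 0.0814 by fry). Size varied between passages, with 733, 106 and 1177 CPM of MX1 in 48 h replicates 1, 2 and 3 against 41.9, 15.7 and 26.8 in their controls. Without control 2 or control 3 the count fell to 5 and 8, and the calls of IFI44L (adjusted p = 0.0578 and 0.0532), MX2 (0.0582 and 0.0538) and MX1 (0.0631 and 0.0577) were lost. OAS1 lost its call without control 2 (0.0503), and XAF1 and TRIM22 lost theirs without any 1 of the controls, 48 h replicate 1 or 48 h replicate 3 (0.0548 to 0.0896). Antigen presentation genes had 1 call among 17 (TAPBP, 0.95 ± 0.22, adjusted p = 0.0106), and 1 adjusted over the list alone. Their camera adjusted p was 0.0945 (adjusted p = 0.781 with an estimated correlation), or 0.0206 with the replicate block, which called 5, among them TAP1 and NLRC5 (adjusted p = 0.0277 and 0.0451).

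Genes of the NRF2 antioxidant response were higher in part. AKR1C2 and AKR1C1, near-identical aldo-keto reductases whose reads may be split between them, rose from 6.68 ± 0.953 to 272 ± 246 CPM (5.35 ± 1.35, adjusted p = 0.0191) and from 12.8 ± 5.75 to 293 ± 258 CPM (4.52 ± 1.22, adjusted p = 0.0244). Of 22 members 11 rose and 0 fell, with 12 higher adjusted over the list alone, a median of 0.96 and a camera adjusted p of 0.000653 (adjusted p = 0.518 with an estimated correlation, 0.0528 by fry). The count was 2, 4 and 3 without control 1, 2 and 3, and 4 without 48 h replicate 1 or replicate 3. AKR1C2 lost its call without control 1, 2 or 3 (adjusted p = 0.0672, 0.0728 and 0.0652), and AKR1C1 without these, 48 h replicate 1 or 48 h replicate 3 (0.0504 to 0.0893).

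Known transcriptional targets of TGF-β rose in part at 48 h. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand), the p21 inhibitor of cyclin-dependent kinases, went from 88.1 ± 6.37 to 371 ± 79.8 CPM (log2 fold change 2.07 ± 0.18, adjusted p = 0.000318). CDKN2B, the p15 inhibitor, rose by 2.54 ± 0.66 (adjusted p = 0.021) and BHLHE40, a transcriptional repressor, by 2.08 ± 0.13 (adjusted p = 4.19e-05). Of 24 tested targets 13 rose and 1 fell, with 15 and 2 adjusted over the list alone, a median of 1.06 and a camera adjusted p of 2.48e-08. This was the only list of the comparison whose call held with an estimated correlation (adjusted p = 0.0328). CDKN2B lost its call without any 1 of the controls, 48 h replicate 1 or 48 h replicate 3 (adjusted p = 0.055 to 0.0775). TGFB1 rose by 1.18 ± 0.20 (adjusted p = 0.00282) and TGFBR1 by 0.70 ± 0.13 (adjusted p = 0.00412), and the log2 fold change of TGFBR2 was -0.09 ± 0.21 (adjusted p = 0.782). Ligands, receptors and SMADs together had 6 rises and 1 fall among 15 genes, the same adjusted over the list alone (camera adjusted p = 0.125).

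Genes of the ID family, inhibitors of basic helix-loop-helix factors, fell. ID3 (ENSG00000117318, chromosome 1, 23557918 to 23559794, minus strand) went from 49.6 ± 20.3 to 2.78 ± 0.813 CPM (-4.17 ± 0.48, adjusted p = 0.000994), and ID1 and ID2 fell by 2.94 ± 0.62 and 2.92 ± 0.55 (adjusted p = 0.0096 and 0.0049). The wider list of ID and BMP response genes had 2 rises and 4 falls among 11, or 3 and 4 adjusted over the list alone, and was not called (camera adjusted p = 0.427). IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002, plus strand), a pro-inflammatory cytokine, went from 25.7 ± 8.39 to 1.15 ± 1.09 CPM (-4.55 ± 0.79, adjusted p = 0.0044) and IL1B from 87.0 ± 4.03 to 7.85 ± 2.66 CPM (-3.46 ± 0.69, adjusted p = 0.00799). IL11, a cytokine of the IL-6 family, rose by 2.21 ± 0.20 (adjusted p = 0.000412). The cytokine and NF-kB list had 2 rises and 6 falls among 28, the same adjusted over the list alone (camera adjusted p = 0.753). It had 4 rises with the replicate block or without 48 h replicate 2, and 3 falls without 48 h replicate 1.

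Matrix and integrin genes rose in part. COL5A1, a fibrillar collagen chain, went from 83.8 ± 9.07 to 581 ± 32.7 CPM (2.79 ± 0.20, adjusted p = 0.000155), and COL1A1 and COL6A3 rose by 2.51 ± 0.55 and 1.93 ± 0.58 (adjusted p = 0.0117 and 0.0312). Of 25 collagen and matrix genes 9 rose and 0 fell (11 higher adjusted over the list alone, median 1.13, camera adjusted p = 8.2e-06; adjusted p = 0.135 with an estimated correlation), and the replicate block called 17. ITGB6, ITGA2 and ITGAV, integrin subunits, rose by 2.65 ± 0.54, 2.26 ± 0.27 and 2.21 ± 0.61 (adjusted p = 0.00835, 0.000809 and 0.0253). Of 14 integrins 8 rose and 0 fell (11 higher adjusted over the list alone, median 1.12, camera adjusted p = 3.39e-05; adjusted p = 0.0851 with an estimated correlation). SERPINE2, a secreted protease inhibitor, rose by 2.60 ± 0.24 (adjusted p = 0.000444) and MMP2, a gelatinase, by 1.82 ± 0.21 (adjusted p = 0.000702), while KLK8, a serine protease, fell by 2.02 ± 0.33 (adjusted p = 0.0027). Proteases and their inhibitors had 10 rises and 4 falls among 35, the same adjusted over the list alone (median 0.75, camera adjusted p = 0.00258; adjusted p = 0.117 with an estimated correlation). The integrin count was 5, 4 and 4 without control 1, 2 and 3 and 5 without 48 h replicate 3, and 6 protease genes rose without control 1 or control 3. ITGAV lost its call without any 1 of the controls, 48 h replicate 1 or 48 h replicate 3 (adjusted p = 0.0543 to 0.0865), COL6A3 without any 1 library other than 48 h replicate 3 (0.0567 to 0.119) and COL1A1 without control 2 (0.0503).

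Mesenchymal markers rose in part at 48 h. TGM2, a transglutaminase, went from 1.43 ± 0.912 to 10.2 ± 4.16 CPM (2.86 ± 0.45, adjusted p = 0.00235). Of 16 mesenchymal markers 6 rose and 0 fell, the same adjusted over the list alone (median 0.91, camera adjusted p = 0.00133; adjusted p = 0.0851 with an estimated correlation). Fibroblast markers had 4 rises among 6, with 5 adjusted over the list alone, among them the protease gene FAP at 2.13 ± 0.46 (adjusted p = 0.01; list camera adjusted p = 0.003, and adjusted p = 0.111 with an estimated correlation), and 2 rises without control 2. The fibroblast list shares COL1A1 and COL6A3 with the matrix list. The intermediate filament gene VIM was at 204 ± 4.0 CPM in controls and 306 ± 139 at 48 h (0.58 ± 0.37, adjusted p = 0.258), the N-cadherin gene CDH2 had a log2 fold change of 0.00 ± 0.40 (adjusted p = 0.996) and the fibronectin gene FN1 one of 2.48 ± 0.97 (adjusted p = 0.0852). FN1 passed with the replicate block (adjusted p = 0.000492) and without control 3 (0.0391). Among transcription factors of the epithelial to mesenchymal transition, SOX4 rose by 1.24 ± 0.20 and SNAI2 by 0.65 ± 0.15 (adjusted p = 0.0025 and 0.00963), 2 of 7 tested and 2 adjusted over the list alone (list camera adjusted p = 0.243). SNAI1 and ZEB1, with 24 and 60 counts over all 9 libraries, were below the level that could be tested.

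Epithelial genes moved both ways. The E-cadherin gene CDH1 was at 295 ± 61.2 CPM in controls and 402 ± 50.8 at 48 h (0.44 ± 0.18, adjusted p = 0.0802), and passed without control 1 (0.0477). FOXA1 fell by 3.04 ± 0.56, EHF by 1.73 ± 0.21 and OVOL2 by 1.23 ± 0.41, all transcription factors of epithelial cells (adjusted p = 0.00426, 0.000828 and 0.0444). Epithelial identity factors had 2 rises and 8 falls among 20 (2 and 9 adjusted over the list alone, median -0.41, camera adjusted p = 0.0199; adjusted p = 0.382 with an estimated correlation). In contrast LAMA3, a laminin chain of the basement membrane, rose by 2.15 ± 0.40 (adjusted p = 0.00436), and the basal keratin KRT15 fell by 2.52 ± 0.37 (adjusted p = 0.00174). Basal keratinocyte genes had 7 rises and 1 fall among 15 (10 and 1 adjusted over the list alone, median 0.82, camera adjusted p = 0.000114; adjusted p = 0.0851 with an estimated correlation). Junction genes had 7 rises and 5 falls among 27 (8 and 6 adjusted over the list alone, camera adjusted p = 0.553). There were 5 falls of identity factors without control 1, control 2, 48 h replicate 2 or 48 h replicate 3, and 0 rises without any 1 library other than 48 h replicate 2. Only 4 basal genes rose without control 2. OVOL2 lost its call without any 1 library (adjusted p = 0.0602 to 0.124). Junction genes had 1 rise and 1 fall without control 2 or control 3, 1 and 2 without 48 h replicate 1, 2 and 3 without 48 h replicate 3, 6 and 2 without control 1 and 7 and 2 without 48 h replicate 2.

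Proliferation genes were lower in step. CCNA2 (ENSG00000145386, chromosome 4, 121816444 to 121823933, minus strand), the cyclin of S phase and G2, went from 253 ± 11.5 to 72.1 ± 20.3 CPM (-1.81 ± 0.44, adjusted p = 0.0157), CDC20, an activator of the anaphase-promoting complex, fell by 2.08 ± 0.51 (adjusted p = 0.0167) and the kinesin gene KIF20A by 1.82 ± 0.45 (adjusted p = 0.0175). Of 35 G2 and mitosis genes 0 rose and 29 fell, or 35 adjusted over the list alone (median -1.50, camera adjusted p = 9.78e-12; adjusted p = 0.474 with an estimated correlation), and 16 fell with the replicate block. E2F2, an activator of S phase genes, fell by 3.01 ± 0.43 (adjusted p = 0.00193), the clamp loader gene RFC3 by 1.96 ± 0.45 (adjusted p = 0.0128) and the replication factor MCM10 by 1.90 ± 0.62 (adjusted p = 0.0471, or 0.0654 with the replicate block). Of 36 S phase and replication genes 0 rose and 28 fell, or 34 adjusted over the list alone (median -1.46, camera adjusted p = 1.42e-12; adjusted p = 0.474 with an estimated correlation). Counts of falls without control 1, 2 and 3 were 10, 10 and 14 for G2 and mitosis and 11, 9 and 12 for S phase. Without 48 h replicate 1, 2 and 3 they were 4, 11 and 23 for G2 and mitosis and 6, 20 and 9 for S phase. MCM10 lost its call without any 1 library (adjusted p = 0.0743 to 0.138), and CCNA2, RFC3, CDC20 and KIF20A without 48 h replicate 1 (0.0607, 0.055, 0.0651 and 0.0674). CDC20 also lost it without control 2 (0.0507), and KIF20A without control 1, control 2 or 48 h replicate 2 (0.0517, 0.0521 and 0.06).

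Histone genes fell with them. HIST3H2BB went from 30.1 ± 4.06 to 1.41 ± 0.165 CPM (-4.42 ± 0.46, adjusted p = 0.000626) and HIST3H2A fell by 3.96 ± 0.39 (adjusted p = 0.000492). Among replication-dependent histone genes, HIST1H1D, HIST1H4C and HIST1H2BK fell by 2.68 ± 0.69, 2.19 ± 0.59 and 2.20 ± 0.47 (adjusted p = 0.0203, 0.0239 and 0.0101), as did HIST1H1A by 3.27 ± 0.78 (adjusted p = 0.016). Of 13 listed histone genes 12 fell and 0 rose, or 13 adjusted over the list alone (median -1.85, camera adjusted p = 2.17e-10; adjusted p = 0.324 with an estimated correlation). Without control 2, control 3, 48 h replicate 1 or 48 h replicate 2, 7 fell. HIST1H1A lost its call without 48 h replicate 1 (adjusted p = 0.0629), HIST1H4C without any 1 library (0.051 to 0.0842), and HIST1H1D without control 2 or 3 or 48 h replicate 1 or 2 (0.0536 to 0.0739). Histone genes are close copies of each other, so reads may be divided between them.

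Further groups changed at 48 h. MXD4, an antagonist of MYC, and KLHL24 rose by 2.58 ± 0.16 and 2.54 ± 0.47 (adjusted p = 4.19e-05 and 0.00573), whereas TXNIP, an inhibitor of thioredoxin and glucose uptake in the same list of FOXO and quiescence genes, fell by 3.40 ± 0.19 (adjusted p = 4.19e-05). That list had 9 rises and 2 falls among 21 (10 and 2 adjusted over the list alone, median 0.73, camera adjusted p = 0.0137; adjusted p = 0.542 with an estimated correlation). The receptor gene LGR6 rose by 3.92 ± 1.11, WNT9A by 2.28 ± 0.28 and WNT7A by 1.84 ± 0.16 (adjusted p = 0.0288, 0.000914 and 0.000318), and WNT pathway genes had 7 rises and 1 fall among 27 (8 and 1 adjusted over the list alone, camera adjusted p = 0.0398; adjusted p = 0.549 with an estimated correlation, and 0.0789 after a GC correction). The actin-associated genes LIMA1, FLNC and PDLIM7 rose by 1.15 ± 0.20, 1.14 ± 0.34 and 0.89 ± 0.25 (adjusted p = 0.00339, 0.0301 and 0.0243), among 6 rises and 1 fall of 23 contractile genes, the same adjusted over the list alone (camera adjusted p = 0.0433; adjusted p = 0.357 with an estimated correlation, and 0.067 after a GC correction). Without control 1, 2 or 3 or 48 h replicate 1, 4 WNT genes rose, and without control 1, control 2 or 48 h replicate 2, 3 contractile genes did. LGR6 lost its call without any 1 library other than 48 h replicate 2 (adjusted p = 0.055 to 0.0975), FLNC without any other than 48 h replicate 1 (0.0515 to 0.101) and PDLIM7 without control 1, control 2 or 48 h replicate 2 (0.0691 to 0.09). ST8SIA1, the GD3 ganglioside synthase, went from 0.552 ± 0.153 to 15.9 ± 11.5 CPM (4.83 ± 1.09, adjusted p = 0.0126), a call lost without control 2 (0.0542). CA9, a carbonic anhydrase induced by hypoxia, fell by 3.30 ± 0.87 (adjusted p = 0.0221), and lost its call without control 2, control 3, 48 h replicate 1 or 48 h replicate 3 (0.0555 to 0.0799), while VEGFA rose by 1.68 ± 0.36 (adjusted p = 0.0083). The hypoxia and glycolysis list had 6 rises and 3 falls among 29, the same adjusted over the list alone, with a median of -0.15, a mean of 0.03 and a camera test in the upward direction (adjusted p = 0.863). Its falls numbered 7 with the replicate block and 1 without control 2, control 3 or 48 h replicate 3, and its rises 3 without control 2 or 3.

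**Figure D2:**
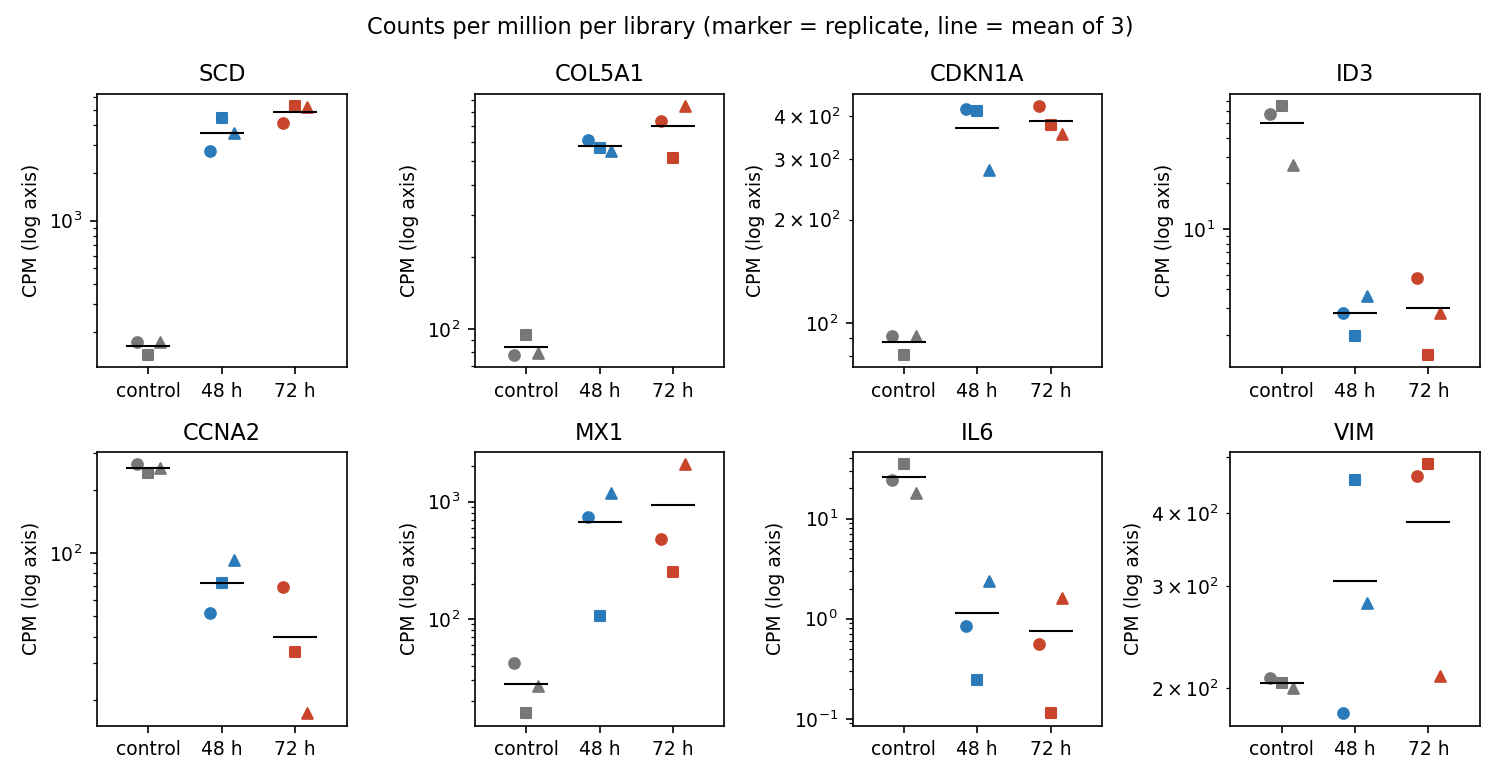
CPM of SCD, COL5A1, CDKN1A, ID3, CCNA2, MX1, IL6 and VIM in each library (log axis), by group; marker shape gives the replicate and the line the mean of 3 libraries. SCD averaged 162 CPM in controls, 3584 at 48 h and 4860 at 72 h, and VIM 204, 306 and 386.

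After 72 h, lipid synthesis genes and many interferon-stimulated, matrix and integrin genes were again higher than in controls, and proliferation and histone genes lower. SCD reached 4860 ± 634 CPM (log2 fold change 4.91 ± 0.25, adjusted p = 3.89e-05), and INSIG1 rose by 3.47 ± 0.42 (adjusted p = 0.000724, n = 3). Of 31 lipid synthesis genes 27 rose and 0 fell, the same adjusted over the list alone (median 1.81, camera adjusted p = 9.99e-17; adjusted p = 0.234 with an estimated correlation). In all, 6152 genes (39.8%) passed, 3151 higher and 3001 lower (2958 and 3202 with a GC correction), and 3023 of the 6152 changed at least 2-fold. At an unadjusted p under 0.05 there were 7680 genes, against 772 by chance, and in 8501 (55.1%) the groups did not overlap, against 10% by chance. No single omitted library moved the count by more than 1.5 times (4111 to 6004). With an estimated correlation 0 of the 36 lists kept a call at 72 h.

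The largest rises at 72 h included genes almost silent in controls. The lectin gene CLEC7A had 0.0896 ± 0.112 CPM in controls and 27.4 ± 45.0 at 72 h (adjusted p = 0.0464), with 2.14, 0.684 and 79.3 CPM in 72 h replicates 1, 2 and 3. LGALS7B, a galectin whose near-identical copy LGALS7 may share its reads, went from 0.130 ± 0.0810 to 15.9 ± 18.3 CPM (adjusted p = 0.00842). WFDC21P, SYT14 and FXYD2 had 0.124 ± 0.0182, 0.20 ± 0.0506 and 0.297 ± 0.0805 CPM in controls and 11 ± 17.6, 10.9 ± 16.4 and 15.9 ± 22.8 at 72 h (adjusted p = 0.0249, 0.025 and 0.0224). In 72 h replicate 3 these 3 genes stood at 31.4, 29.8 and 42.2 CPM, against at most 3.44 CPM in the other 72 h libraries. CLEC7A, SYT14 and FXYD2 lost their calls without 72 h replicate 3 (adjusted p = 0.277, 0.0554 and 0.055), and these and WFDC21P also without control 1, 2 or 3 (0.0724 to 0.132). At 48 h, CLEC7A and FXYD2 did not pass (adjusted p = 0.104 and 0.112), but did with the replicate block (adjusted p = 0.000832 and 0.033).

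Many interferon-stimulated genes were higher than in controls at 72 h too. IFI44L reached 450 ± 559 CPM (7.22 ± 1.55, adjusted p = 0.00762) and MX1 936 ± 991 (5.06 ± 1.11, adjusted p = 0.00842), and MX2 and XAF1 rose by 5.85 ± 1.25 and 6.03 ± 1.38 (adjusted p = 0.00743 and 0.00975). Of 37 tested 22 rose and 0 fell, or 28 adjusted over the list alone (median 2.59, camera adjusted p = 7.23e-08; adjusted p = 0.629 with an estimated correlation, and 0.0673 by fry), and the median was 1.23 without 72 h replicate 3. MX1 stood at 484, 252 and 2073 CPM in 72 h replicates 1, 2 and 3. Antigen presentation genes had 9 rises and 1 fall among 17 (10 and 1 adjusted over the list alone, median 1.30, camera adjusted p = 0.0122; adjusted p = 0.656 with an estimated correlation). TAPBP, which tethers class I molecules to the peptide transporter, rose by 1.36 ± 0.22 (adjusted p = 0.00163), the transporter gene TAP1 by 2.14 ± 0.63 (adjusted p = 0.0271) and the class I transactivator NLRC5 by 2.09 ± 0.72 (adjusted p = 0.0477). Their rises numbered 5, 3 and 4 without control 1, 2 and 3 and 5 without 72 h replicate 3, where the list median was 0.73, and without any 1 of these libraries TAP1 (0.0628 to 0.092) and NLRC5 (0.0951 to 0.172) lost their calls. NRF2 genes had 3 rises and 1 fall among 22, the same adjusted over the list alone (camera adjusted p = 0.501), with 6 rises and 2 falls in the replicate block and 5 rises without 72 h replicate 2. AKR1C1 rose by 4.39 ± 1.21 (adjusted p = 0.0212), a call lost without any 1 control or 72 h replicate 3 (0.0523 to 0.0775), and AKR1C2 was at 69.3 ± 91.9 CPM (adjusted p = 0.0599, or 0.0333 without 72 h replicate 2).

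Part of the TGF-β targets, matrix genes and integrins rose at 72 h as well. CDKN1A rose by 2.14 ± 0.18 and CDKN2B by 3.08 ± 0.67 (adjusted p = 0.000184 and 0.00799), and 14 of 24 targets rose and 1 fell (15 and 1 adjusted over the list alone, median 1.12, camera adjusted p = 2.66e-06; adjusted p = 0.0626 with an estimated correlation). TGFB1 rose by 1.26 ± 0.20 (adjusted p = 0.00142) and TGFBR1 by 0.42 ± 0.13 (adjusted p = 0.0245), and TGFBR2 was at 0.05 ± 0.21 (adjusted p = 0.871). COL5A1, COL1A1 and COL6A3 rose by 3.06 ± 0.20, 2.29 ± 0.55 and 1.86 ± 0.58 (adjusted p = 7.15e-05, 0.0122 and 0.0289). Of 25 collagen and matrix genes 16 rose and 0 fell (18 higher adjusted over the list alone, median 1.47, camera adjusted p = 0.000115; adjusted p = 0.255 with an estimated correlation). Integrins had 10 rises among 14 (12 adjusted over the list alone, median 1.47, camera adjusted p = 3.63e-05; adjusted p = 0.0921 with an estimated correlation), with ITGA2 at 2.47 ± 0.27, ITGB6 at 2.55 ± 0.54 and ITGAV at 2.19 ± 0.61 (adjusted p = 0.000411, 0.00694 and 0.0209). SERPINE2 rose by 3.49 ± 0.25 (adjusted p = 0.000144) and MMP2 by 2.29 ± 0.21 (adjusted p = 0.000223), within 17 rises and 5 falls of 35 proteases and inhibitors (20 and 5 adjusted over the list alone, median 0.94, camera adjusted p = 0.00166; adjusted p = 0.14 with an estimated correlation). TGM2 and P4HA2, a prolyl hydroxylase of collagen, rose by 2.52 ± 0.45 and 1.11 ± 0.14 (adjusted p = 0.00261 and 0.000718), LOXL3, a lysyl oxidase, fell by 1.17 ± 0.40 (adjusted p = 0.0422), and matrix crosslinking genes had 6 rises and 1 fall among 18, the same adjusted over the list alone (camera adjusted p = 0.0488; adjusted p = 0.345 with an estimated correlation, 0.0904 with the replicate block and 0.151 after a GC correction). Without control 1, control 3 or 72 h replicate 2, 3 crosslinking genes rose, without control 1 or control 2, 6 integrins did, and without control 2, 10 matrix genes did, while 2 matrix genes fell without 72 h replicate 3. TGFBR1 lost its call without control 2, control 3, 72 h replicate 1 or 72 h replicate 2 (0.0532 to 0.102), COL6A3 without these 4 (0.064 to 0.109), LOXL3 without any 1 library other than 72 h replicate 2 (0.0788 to 0.0995) and ITGAV without any 1 control (0.0599 to 0.0721).

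Mesenchymal and epithelial genes again moved in part. VIM stood at 386 ± 153 CPM (0.92 ± 0.37, adjusted p = 0.0757), and passed without 72 h replicate 3 (0.0129), where it was at 210 CPM against 463 and 485 in 72 h replicates 1 and 2. CDH1 had a log2 fold change of 0.32 ± 0.18 (adjusted p = 0.165), CDH2 of -0.48 ± 0.41 (adjusted p = 0.368) and FN1 of 2.47 ± 0.97 (adjusted p = 0.0737), and FN1 passed with the replicate block (0.000247) and without control 3 (0.0289). Of 16 mesenchymal markers 7 rose and 0 fell, the same adjusted over the list alone (median 1.14, camera adjusted p = 0.00184; adjusted p = 0.109 with an estimated correlation), and of 6 fibroblast markers 4 rose, or 6 adjusted over the list alone (camera adjusted p = 0.00184; adjusted p = 0.109 with an estimated correlation). Epithelial identity factors had 3 rises and 9 falls among 20 (3 and 10 adjusted over the list alone, median -0.47, camera adjusted p = 0.0441; adjusted p = 0.534 with an estimated correlation), with 1 rise without control 2. FOXA1, OVOL2 and EHF fell by 3.29 ± 0.57, 1.59 ± 0.41 and 1.01 ± 0.20 (adjusted p = 0.00226, 0.0133 and 0.00409) and the keratin KRT80 by 3.39 ± 0.49 (adjusted p = 0.00137). LAMA3 rose by 2.48 ± 0.40 (adjusted p = 0.0017), KRT15 fell by 2.40 ± 0.36 (adjusted p = 0.00126), and basal keratinocyte genes had 7 rises and 1 fall among 15 (8 and 1 adjusted over the list alone, median 0.71, camera adjusted p = 0.0173; adjusted p = 0.238 with an estimated correlation). SNAI2 rose by 0.42 ± 0.15 (adjusted p = 0.0409), and lost its call without any 1 library of the comparison other than 72 h replicate 2 (0.0782 to 0.152).

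Cell cycle genes were lower at 72 h in nearly every member. Of 35 G2 and mitosis genes 35 fell, and 35 adjusted over the list alone (median -2.23, camera adjusted p = 1.97e-21; adjusted p = 0.319 with an estimated correlation). Of 36 S phase genes 33 fell and 0 rose, with 34 falls adjusted over the list alone (median -1.80, camera adjusted p = 1.26e-15; adjusted p = 0.408 with an estimated correlation), and of 13 histone genes 13 fell, and 13 adjusted over the list alone (median -2.23, camera adjusted p = 7.24e-11; adjusted p = 0.285 with an estimated correlation). CCNA2 stood at 39.9 ± 26.3 CPM (-2.66 ± 0.45, adjusted p = 0.00281), and CDC20 and KIF20A fell by 2.54 ± 0.52 and 2.77 ± 0.47 (adjusted p = 0.00591 and 0.00277). E2F8, an E2F family repressor, fell by 3.81 ± 0.48, E2F2 fell by 3.31 ± 0.44, RFC3 by 2.28 ± 0.46 and MCM10 by 2.36 ± 0.63 (adjusted p = 0.000799, 0.000906, 0.00536 and 0.0182), and MCM10 lost its call without 72 h replicate 2 (0.0527). Among histone genes HIST1H4F fell by 3.41 ± 0.75, HIST1H1A by 3.59 ± 0.80 and HIST3H2A by 3.52 ± 0.37 (adjusted p = 0.00859, 0.00864 and 0.000392). IL6 fell by 5.09 ± 0.81 (adjusted p = 0.00225), IL1B by 3.54 ± 0.70 (adjusted p = 0.00537) and ID3 fell by 4.05 ± 0.48 (adjusted p = 0.000663). FOXO and quiescence genes had 10 rises and 2 falls among 21 (11 and 2 adjusted over the list alone, median 1.22, camera adjusted p = 0.0122; adjusted p = 0.629 with an estimated correlation), with 5 falls and a median of 0.78 without 72 h replicate 3. MXD4 and KLHL24 rose by 2.45 ± 0.16 and 2.51 ± 0.47 and TXNIP fell by 2.93 ± 0.19 (adjusted p = 6.32e-05, 0.00427 and 6.32e-05).

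**Figure D3:**
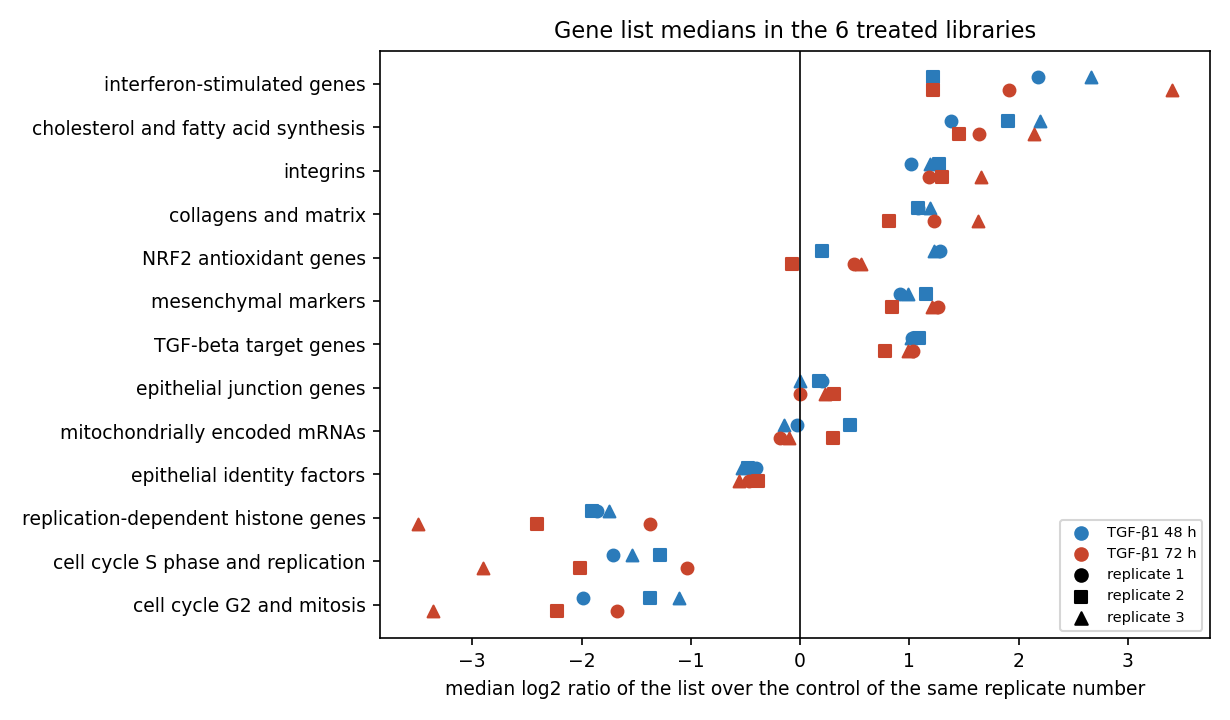
Median log2 ratio of 13 gene lists in each treated library over the control of the same replicate number (x axis, log2); colour gives the time and marker shape the replicate. The interferon-stimulated list lies between 1.22 and 3.40 and the G2 and mitosis list between -3.36 and -1.11.

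The 48 h and 72 h groups were compared directly to ask which genes differed between the times. The median log2 difference at 72 h was -0.77 for G2 and mitosis genes and -0.68 for NRF2 genes, and 0.62 for antigen presentation genes. Passages differed. Over the own-passage control, the G2 and mitosis median went from -1.99 at 48 h to -1.67 at 72 h in replicate 1, from -1.37 to -2.23 in replicate 2 and from -1.11 to -3.36 in replicate 3. Antigen presentation genes went from 0.53 to 0.77, 0.88 to 0.86 and 0.75 to 2.00 in these replicates, so most of their difference lay in 72 h replicate 3. NRF2 genes fell in each, from 1.28 to 0.50, 0.20 to -0.07 and 1.23 to 0.56. CCNA2 was at 72.1 ± 20.3 CPM at 48 h and 39.9 ± 26.3 at 72 h, and AKR1C2 at 272 ± 246 and 69.3 ± 91.9 (n = 3). edgeR called 0 genes (smallest adjusted p = 0.466), with 1382 at an unadjusted p under 0.05 against 772 by chance, while DESeq2 called 50, 33 higher and 17 lower. Without the filter on low counts edgeR called 211. In 1890 genes (12.2%) the groups did not overlap, against 10% by chance. By camera 8 lists passed, and 0 with an estimated correlation or by fry. G2 and mitosis genes had an adjusted p of 9.7e-23 (adjusted p = 0.658 with an estimated correlation) and NRF2 genes one of 6.93e-09 (adjusted p = 0.658 with an estimated correlation), with 5 NRF2 genes lower and 0 G2 and mitosis genes adjusted over the list alone. Interferon-stimulated genes had a median of 0.48 (camera adjusted p = 0.114, 0.0294 with the replicate block and 0.976 with an estimated correlation).

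Fold changes at the 2 times were alike across genes. IL6, ID3, TXNIP and COL5A1 lay close to equal change on the plot of both fold changes, and AKR1C2 lay further out at 48 h (5.35) than at 72 h (3.37). Both comparisons use the same controls, which alone makes their fold changes alike. The correlation across 15440 genes, which are not independent replicates, was 0.913 (Pearson) and 0.896 (Spearman), against means of 0.503 (Pearson) and 0.466 (Spearman) in 20 simulations of unchanged groups sharing controls. The covariance was 0.811, against 0.0740 in those simulations, a difference of 0.737. The simulations left out the shared passages, which may raise the values without change. Deviations at 48 h and 72 h correlated at -0.03, 0.49 and 0.49 in replicates 1, 2 and 3. Calls in both comparisons numbered 1995 higher and 2140 lower, against 470 and 482 for independent lists, and 0 genes were called in opposite directions. The simulations shared 0 calls, which is no measure of overlap, since they called at most 2 genes. These 4135 genes were 86.5% of the 48 h calls, with 644 called at 48 h alone and 2017 at 72 h alone. In fits of only the 2 groups compared the 48 h count was the larger, with 6161 genes against 5651 at 72 h. The counts therefore do not show that more genes changed at 72 h. Independent lists leave out the shared controls, and 3 controls cannot be split into parts of at least 2, so part of the excess over such lists may come from the shared controls.

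**Figure D4:**
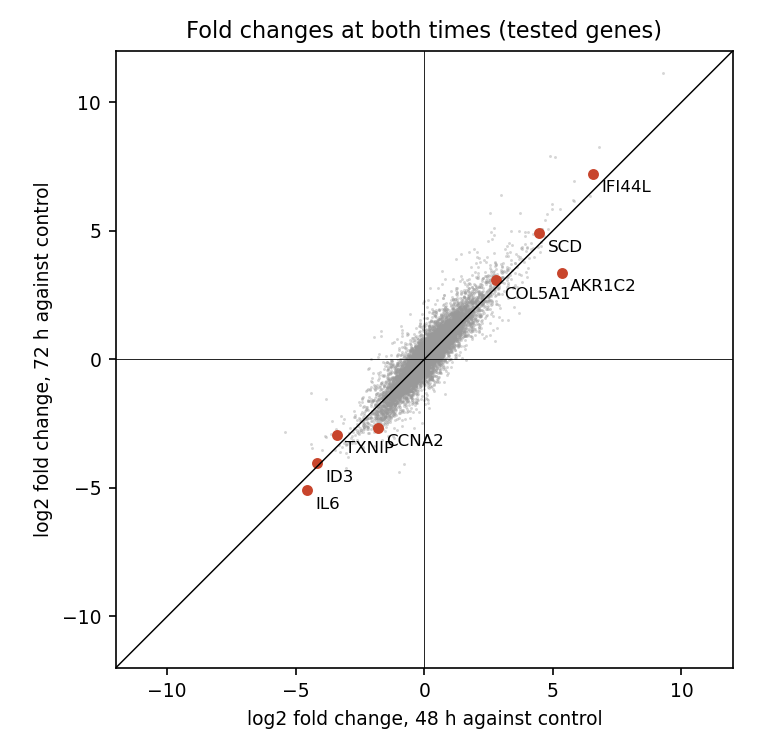
Log2 fold change of tested genes at 72 h (y axis) against that at 48 h (x axis), each against control; grey points are genes, red points are named genes and the diagonal marks equal change. Across the 15440 tested genes Pearson's r was 0.913, and AKR1C2 lies off the diagonal at 5.35 and 3.37.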

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

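The tests of one library, leukocyte RNA, serum withdrawal, library scaling, GC content and the size of the change in 72 h replicate 3, and the counts of other splits, were chosen only after the results were seen. The list tests between times were planned, and the bound for nuclear RNAs was set before its value was known.

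Several gene lists differed between 72 h and 48 h of TGF-β1 by the planned camera test of that difference, although edgeR called 0 single genes (1382 at an unadjusted p under 0.05; DESeq2 called 50). The median log2 difference at 72 h was -0.77 for G2 and mitosis genes (adjusted p = 9.7e-23), -0.68 for NRF2 antioxidant genes (adjusted p = 6.93e-09) and -0.31 for S phase genes (adjusted p = 2.32e-05). It was 0.62 for antigen presentation genes (adjusted p = 0.0272), -0.10 for YAP/TAZ targets (adjusted p = 0.0353), -0.29 for replication-dependent histone genes (adjusted p = 0.0353), -0.17 for basal keratinocyte genes (adjusted p = 0.0472) and -0.22 for Notch pathway genes (adjusted p = 0.0472). With an estimated correlation the adjusted p-values of these 8 lists lay between 0.658 and 0.815, and by fry between 0.579 and 0.767. Over own-passage controls, only the NRF2 and basal lists moved in 1 direction in each passage. In replicate 1 the G2 and mitosis median went from -1.99 at 48 h to -1.67 at 72 h, that of S phase genes from -1.71 to -1.04 and that of histone genes from -1.86 to -1.37, against the group difference. In replicate 3 they went from -1.11 to -3.36, from -1.54 to -2.90 and from -1.75 to -3.50. Antigen presentation went from 0.53 to 0.77, 0.88 to 0.86 and 0.75 to 2.00 in replicates 1, 2 and 3, so its difference lay mostly in 72 h replicate 3. No test of single outlying libraries was made in these groups of 3.

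Interferon-stimulated genes were at the median higher in the 6 treated libraries than in their own-passage controls, with list medians from 1.22 to 3.40 on the log2 scale. The lowest of these medians, 1.22, speaks against a single library as the source. Leukocyte RNA is unlikely, since the 4 tested leukocyte markers had a median of -1.11 at 72 h, the highest of the 16 listed reached 1.30 CPM (CSF1R) in a treated library, and only ITGAM and CD163 passed, both as falls. ITGAM lost its call without control 2, control 3, 72 h replicate 1 or 72 h replicate 2 (adjusted p = 0.0557 to 0.0772), and CSF1R passed as a rise without 72 h replicate 2 (1.54, adjusted p = 0.0238). A GC trend is unlikely to be the whole cause, since the 48 h median was 2.29 without and 2.27 with its correction. Each group held the same 3 passages, and the lowest median over an own-passage control was 1.22, so passage alone does not give the rise, although its size differed between passages. Treatment, the change of medium and time in culture remain open, and no test here separates them.

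Proliferation genes were lower and lipid synthesis genes higher at both times. Serum withdrawal could give both, and it cannot be told apart from TGF-β1 here, because 0 control libraries have labels that state a medium without serum. Time in culture cannot be told apart either, since the titles of the controls carry a time of 0 h. A GC trend does not account for the pattern, since with its correction the smallest absolute median of the S phase, G2 and mitosis and lipid lists at both times was 1.46. The choice among scaling factors does not either, with a smallest absolute median of 1.41 under DESeq2 size factors or upper-quartile factors. Both put the median of all genes near 0 against control (0.0845 at most), so this test could not show a shift shared by most genes.

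The 72 h library of replicate 3 lay apart from the other treated libraries, with log2 ratios over the mean of the other 72 h libraries of 1.86 for MALAT1 and 2.43 for NEAT1. A general rise was not seen in 11 other RNAs listed as nuclear, with a median ratio of 0.0852 (-1.32 to 1.16, with 6 above 0). Where these RNAs lie in these cells was not measured. Their ratios spread both ways, with KCNQ1OT1 at 0.67 and MIR17HG at -1.32, so this median cannot exclude a larger share of nuclear RNA. The distance of 72 h replicate 3 from the other 72 h libraries with the GC trend removed was 0.994 of its value before (0.803 against 0.807), while those 2 libraries lay 0.507 apart. A candidate explanation is a larger form of the change in the other passages. The slope was taken over 5682 genes called at 72 h without this library, so chosen largely for a change in passages 12 and 13. Across them this library's change over control 3 had a slope of 1.21 on the mean change in those passages (r = 0.884). That is just above the bound of 1.2, so the slope gives this candidate little weight. Slopes were 0.85 to 1.14 in the other treated libraries. Each library of passages 12 and 13 was set against a mean that left out only that library. The other library of its passage, taken over the same control, stayed in that mean. The mean joined 48 h and 72 h libraries over genes called at 72 h, so slopes of 72 h libraries, the 1.21 among them, may be raised. They were 0.924 in 72 h replicate 1 and 1.14 in 72 h replicate 2. The 48 h library of the same passage also lay below 0 on the second principal component (-24.4, against -42.7), while the treated libraries of passages 12 and 13 lay at 6.60 to 41.0. Whether passage or chance in this culture lies behind it was not tested.

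With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In fits of the 2 groups alone, the real split of control and 48 h libraries gave 6161 genes and the highest other split 0, so 1 of 10 gave as many. For control and 72 h the real split gave 5651 and the highest other 0, again 1 of 10. Each other split mixed control and treated libraries on both sides, which raises the spread within each side. Its 0 calls are therefore no measure of chance. For 48 h and 72 h all 10 gave 0.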

How the results depend on the processing

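The corrections for GC content and exon length, and list counts under them, were chosen after seeing the data. The direction with more calls turned at 48 h with DESeq2 (2766 higher, 2599 lower), its size factors, upper-quartile factors, no filter or the replicate block (2565 and 2548), and at 72 h with GC or length corrections (2856 and 3262 for length), among others. Of 258 named gene results none of the 218 passing ones changed sign, while some of the 40 others did (TGFBR2 and CDH2 among them). Nearly all calls had no overlap between the groups' libraries, 4756 of 4779 at 48 h and 6096 of 6152 at 72 h. Leaving out libraries could therefore hardly turn their sign. Of the 218, 88 passed in every setting and 130 lost the call in at least 1. Of the 40 not passing, 21 gained it in at least 1. A 2-fold threshold left 2158 genes at 48 h and 3023 at 72 h, by construction. Leaving out libraries or replicate numbers gave 765 to 4599 genes at 48 h and 2602 to 6004 at 72 h, where fewer samples enter, and 0 at 72 h against 48 h. For 72 h against 48 h DESeq2 called 50 and edgeR without a low-count filter 211, against 0, and the cause was not tested. With an estimated correlation 1, 0 and 0 lists passed at 48 h, at 72 h and between the times, against 17, 16 and 8. By fry, 17, 18 and 0 lists passed. Both allow for correlation between genes, but fry does not compare a list with other genes. The replicate block, a pairing by passage, called 5113 genes at 48 h and 6465 at 72 h (4514 and 5905 of them shared with the fit without it), 0 between the times, 18, 15 and 9 lists, and a correlation of fold changes of 0.916. Beyond the calls given beside the results it changed that of NEAT1 at 48 h (adjusted p = 0.0592), KRT16 at both times (0.0105 and 0.00486) and HES5 at 72 h (0.0365), and no other call of a named gene. Omission of 1 control gave correlations of 0.908 to 0.917, against 0.913. Other settings kept the counts within 1.5 times, at 4741 to 6161 and 5651 to 6585 genes and 15 to 18 lists against control. No setting put the median of all genes further than 0.085 from 0, which the scaling itself largely sets. With upper-quartile factors 2 lists with medians near 0 flipped sign, the mitochondrially encoded mRNAs at both times and the cytokine and NF-kB list at 48 h. At 12544690 to 20438727 counts and 3 libraries per group, 29.9% to 38.8% of 2-fold changes were recovered in simulations with few changed genes; in the data, calls under 2-fold were common.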

Other observations

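The families and genes below were defined by symbol and chosen after their values were seen, from 36 families examined, and all tests here were chosen then. Laminin genes rose in part. LAMB3 went from 1499 ± 83.0 CPM in controls to 5512 ± 1920 at 48 h and 7067 ± 1902 at 72 h (SD, n = 3; log2 fold changes 1.88 ± 0.30 and 2.24 ± 0.30, adjusted p = 0.00236 and 0.000811), and LAMB2 rose by 2.26 ± 0.20 and 2.76 ± 0.20 (adjusted p = 0.000348 and 0.000147). Of 10 tested laminins 6 rose at 48 h and 8 at 72 h, and 0 fell (camera adjusted p = 0.000311 and 0.00025; adjusted p = 0.219 and 0.175 with an estimated correlation), with 3 rises at 48 h without control 2. Protocadherin genes, cell adhesion molecules in clusters of overlapping paralogs whose reads may be divided, rose in 15 of 31 at 48 h and 18 at 72 h, and 0 fell, with medians of 1.18 and 1.30 and of 1.17 at both times after a GC correction (camera adjusted p = 9.6e-08 and 1.8e-06; adjusted p = 0.484 and 0.48 with an estimated correlation). PCDH1, outside the clusters, rose by 1.42 ± 0.29 and 2.67 ± 0.30 (adjusted p = 0.007 and 0.000468). The protocadherin count at 48 h was 9, 9 and 8 without 48 h replicate 1, control 2 and control 3, and at 72 h 11 without control 3 or 72 h replicate 3, and the 72 h median was 0.76 without 72 h replicate 3.

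Part of the ribosomal protein genes fell, with medians of less than 2-fold. Cytosolic ones had 1 rise and 19 falls among 81 at 48 h and 1 and 54 at 72 h, with medians of -0.44 and -0.73 (camera adjusted p = 2.68e-06 and 2.77e-11; adjusted p = 0.578 and 0.48 with an estimated correlation). Mitochondrial ones had 0 rises and 45 falls among 78 at 48 h and 1 and 45 at 72 h, with medians of -0.48 and -0.46 (camera adjusted p = 1.44e-09 and 8.88e-08; adjusted p = 0.304 and 0.292 with an estimated correlation). The 48 h falls of cytosolic genes numbered 7, 4 and 9 without control 1, 2 and 3 and 9, 9 and 7 without 48 h replicate 1, 2 and 3, and those of mitochondrial genes 26 without control 2 and 28 without 48 h replicate 1. At 72 h without control 2 the cytosolic falls numbered 23. ALDH1A3, a retinaldehyde dehydrogenase, went from 420 ± 81.3 CPM to 49.0 ± 6.04 and 46.2 ± 18.3 (-3.10 ± 0.28 and -3.18 ± 0.29, adjusted p = 0.000444 and 0.000221).

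Neighbours on chromosome 9p21 differed from each other. Near CDKN2B, which rose at both times, the interferon epsilon gene IFNE (21480839 to 21482313, minus strand, GRCh38) went from 0.553 ± 0.0623 CPM to 8.27 ± 2.45 and 7.73 ± 1.12 (3.89 ± 0.30 and 3.79 ± 0.30, adjusted p = 0.000197 and 0.000147). The host transcript MIR31HG (21455642 to 21559669, minus strand), which overlaps IFNE on the same strand so that their reads are not fully separable, rose by 1.73 ± 0.23 and 1.97 ± 0.23 (adjusted p = 0.00112 and 0.000478). MTAP had log2 fold changes of -0.13 ± 0.23 and -0.44 ± 0.23 (adjusted p = 0.688 and 0.147, or 0.0409 at 72 h without 72 h replicate 1) and CDKN2A of 0.18 ± 0.28 and 0.42 ± 0.28 (adjusted p = 0.647 and 0.254, or 0.013 at 72 h without 72 h replicate 2).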
